A study of Mus musculus with 6 samples.

How the data were processed

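Gene expression was measured on one-colour arrays, on which biotin-labelled RNA of 1 sample is hybridised to each array and read as brightness per probe set. The samples were mouse CD4+CD25- T cells sorted by flow cytometry, activated on plate-bound antibodies against CD3 and CD28, infected with a retroviral vector and collected 5 days later. Per the labels, the cultures held 10% serum at 7% CO2. The 6 arrays formed 3 groups of 2 biological replicates, as the labels give them: wild-type B6 cells with the empty vector, miR-17-92 deficient cells with the empty vector, and deficient cells with a vector for miR-17.

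The deposited values were log2 probe set intensities made by the authors with RMA, per the submitters' processing notes, which gave no version. RMA subtracts background, makes the arrays' distributions alike by quantile normalization and summarises the probes of a set on the log2 scale. The log base was taken from this convention and from the range of the values, since it was not given in the sources used here. Because quantile normalization equalises the arrays, a change shared by most transcripts would not be seen in these values. Array medians lay between 5.71 and 5.76 and lower quartiles between 3.99 and 4.17. The number of arrays, 2 per group, limits the precision.

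The table held 22690 probe sets, of which 64 were controls, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 were unnamed here. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, used for names and for which genes neighbour each other. No symbol changed, and the identifiers of 29 probe sets were not in that table. Only probe sets with 1 symbol were used. For the 4956 genes with more than 1 probe set, the set with the highest mean over all arrays stood for the gene, which left 12393 genes. Of 115 named genes, 65 had several probe sets, none had a set of opposite sign beyond 0.25 log2 units between deficient mock and wild-type mock cells, and 10 rested on a set that can match several genes. Transcripts of the miR-17-92 cluster were not analysed here.

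All 6 arrays were fitted in one linear model in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend), so that the 3 groups shared one estimate of spread with 3 residual degrees of freedom and 4.69 prior ones. The comparisons were deficient mock minus wild-type mock, deficient miR-17 minus deficient mock, and deficient miR-17 minus wild-type mock. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9.

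The design, the alternatives and the rule for named genes were fixed before the data were examined. For each of the first 2 comparisons the rule took the 8 largest called differences in each direction among genes whose groups did not overlap, leaving out predicted genes and antigen receptor segments, and filled any shortfall with the smallest unadjusted p-values. It added a fixed set of genes, of which 1 is not reported here (the others were Tgfbr2, Creb1, Bcl2l11, Cdkn1a, Rbl2, E2f1, Ifng, Tbx21 and Foxp3), the 4 members with the smallest p of each called list, up to 4 called members of each other list, the 10 reciprocal genes with the smallest larger p (predicted genes were left out there too, which the rule did not state), and for the last comparison the 3 largest called differences in each direction. Other members of a list, such as Gata3 and Il4, were named as examples after their values were seen.

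Gene lists were written from general knowledge, 34 in all: published targets of the miR-17 and miR-19 families, helper T cell lineages, activation, cell cycle and its inhibitors, survival and growth signalling, metabolism, stress and interferon responses, housekeeping groups, markers of other cell types, sex-linked transcripts, the cluster's transcripts and the hosts of its paralogs. The 31 lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 31 lists. A call lost with an estimated correlation need not mean correlated genes. For TGF-beta signalling in deficient mock against wild-type mock the estimate, -0.0107, lay below the preset, yet the unadjusted camera p rose from 0.00282 to 0.0462. A list's mean shift is the mean log2 difference of its members minus that of all other genes. Member counts were also adjusted over the list alone.

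Genes moving one way without the cluster and back with miR-17 were counted at an unadjusted p under 0.05 in both comparisons. Because both use the deficient mock arrays, 100 sets of 6 unchanged arrays were simulated with the fitted spread of each gene and analysed in the same way. The same simulation served the comparisons that share the wild-type arrays.

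The procedure was tested on simulated arrays of the 12393 genes, in 10 runs with 200 changed genes each. For deficient mock against wild-type mock it called 4.4% of genes changed 1.25-fold, 46.2% at 1.5-fold, 95.8% at 2-fold and 99.6% at 4-fold, with 11.5 unchanged genes called per run, and found a list of 31 genes shifted by -0.15 in 10 of 10 runs. For deficient miR-17 against deficient mock the shares were 5%, 44.2%, 94.8% and 100%, with 9.5 unchanged genes called per run, and the shifted list was found in 9 of 10 runs. None of the 30 unshifted lists per run was called by camera, in simulated data without correlation between genes. The simulated arrays were also independent, whereas differences between replicates 1 and 2 correlated between the real groups at 0.429 to 0.634. The shares therefore need not hold for the real arrays.

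Alternatives were: each array left out in turn, with a lone array assumed to vary like the other groups, the replicate number as a term, the lowest 25% or 50% of genes by mean left out, quantile normalization again or median centring, the mean of a gene's probe sets or every probe set on its own, eBayes without trend or robust, only the compared groups in the fit, array weights, an adjusted p under 0.10, a minimum of 1.5-fold, an estimated correlation and fry. Planned tests of miR-17 seed matches in 3' untranslated regions were left out, since no transcript sequence was used here. Groups of 2 arrays are too small for a test of outlying arrays within a group or for regrouping the arrays.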

Results

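The arrays measured mRNA in mouse CD4+CD25- T cells, helper T cells freed of CD25-bearing cells by flow sorting. The cells had been stimulated through the T cell receptor and CD28 by plate-bound antibodies, infected with a retroviral vector that carries a transgene into dividing cells, and harvested 5 days later. The 6 arrays formed 3 groups of 2 biological replicates. Wild-type B6 cells with the empty vector made up the wild-type mock group, and cells lacking the miR-17-92 cluster, a set of microRNAs cut from 1 transcript, made up the other groups. These deficient cells carried either the empty vector (deficient mock) or a vector expressing miR-17, a member of the cluster (deficient miR-17). Array medians lay between 5.71 and 5.76 log2 units, and the arrays of a group correlated across probe sets at r = 0.994, 0.995 and 0.994. The cluster's own transcripts were not analysed here, so these arrays gave no check of the deletion itself. With 2 arrays per group the precision was limited, and an exact permutation test could not go below p = 0.333. Calls came from limma, whose p-values set each difference against a spread estimated partly from the gene's own arrays and partly from all genes. Without a term for the replicate number, differences by number that the groups share stay in that spread. Differences are log2 ± SE from that fit with n = 2 arrays per group, and calls were made at limma's adjusted p under 0.05 among 12393 genes.

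The first comparison, deficient mock against wild-type mock, asked which transcripts differ when the cluster is missing. Il10, the gene of an anti-inflammatory cytokine, read lower in deficient cells (-4.59 ± 0.18, limma adjusted p = 0.000135), with means of 8.17 and 3.58. The latter lies below the lower quartile of every array (3.99 to 4.17), where background can set the reading, so the difference is one of readings and not a measured ratio of transcripts. Means within or below that range, of which the same holds, were read for Gem (4.01), Il5 (3.82) and Havcr2 (3.62) in deficient mock and Ifit1 (3.95) in wild-type mock cells. Ctla2b, related to cysteine protease inhibitors, was lower by -3.60 ± 0.16 and Serpinf1, a secreted serpin, by -3.57 ± 0.29. Gem, a small GTPase, was lower by -2.92 ± 0.13 and Sdc4, a cell-surface proteoglycan, by -2.73 ± 0.19. Dimmer probe sets read -0.46 for Sdc4 and -1.92 for Serpinf1. Selenbp1 (-2.67 ± 0.61, but -1.73 without deficient mock replicate 1), Tgfb3, a TGF-beta ligand (-2.48 ± 0.34), and Ier3, an immediate early gene (-2.36 ± 0.44), completed the 8 largest decreases under the fixed rule. That rule ranked only called genes whose groups did not overlap. Limma adjusted p lay between 0.000138 and 0.0431 for the 7 besides Il10. The largest increases under that rule were in Ifitm3 (3.62 ± 0.71) and Rtp4 (3.30 ± 0.43), both induced by interferon, in Drc1, a ciliary dynein regulator (2.78 ± 0.17), and in Il2, the T cell growth factor (2.63 ± 0.54). They were followed by Ifit1 (2.24 ± 0.42), Ms4a4c (2.19 ± 0.13), Rexo2 (1.81 ± 0.10) and Itih5 (1.66 ± 0.28). The limma adjusted p of these 8 lay between 0.000318 and 0.0317, and the probe set of Ms4a4c is of a kind that can match related genes.

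In all, 464 genes were higher and 346 lower in deficient mock cells, and 161 of these 810 differed at least 2-fold, 52 of them higher and 109 lower. At limma's unadjusted p under 0.05 there were 2671 genes, where chance gives 620 for independent arrays. The arrays of the 2 groups did not overlap for 49.9% of genes, where chance gives 33.3% for independent arrays. Differences between replicates 1 and 2 correlated across genes at 0.429 between these groups, so neither is an exact baseline. Most calls ended in at least 1 of the fits that left out an array. Of the 810, 92 were still called without wild-type mock replicate 1 and 307 without replicate 2. Without deficient mock replicate 1, 259 were still called, and without replicate 2, 93. The share of higher genes among the calls was 57.3% with all arrays, 22.8% without wild-type mock replicate 1 and 24.2% without deficient mock replicate 2. The 61 genes called in each of these 4 fits, 16 higher and 45 lower, included Il10, Ctla2b, Serpinf1, Gem, Sdc4, Drc1, Ms4a4c and Rexo2, whereas Ifitm3, Rtp4, Il2, Ifit1, Itih5, Selenbp1, Tgfb3 and Ier3 lost the call in at least 1 of them. Of the 80 called genes that the fixed rule named, 19 were called in all 4 fits, and besides those above they were Akap12, Batf, Ccng2, Ctla4, Ifi27l2a, Ighm, Il7r, Slc2a3, Stat4, Tarbp2 and Txnip.

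Genes of the Th2 program, which drives the response to helminths and allergens, were lower in deficient cells as a group (11 measured, mean shift against the other genes -1.09, median -0.74, camera adjusted p = 2.42e-05 with the preset correlation, adjusted p = 0.450 with an estimated correlation). Il10, with its low reading, adds the most to that mean. Of the 11, 6 were lower, 0 were higher and 5 did not pass with limma's adjusted p over all genes, and 6 were lower when adjusted over the list alone. The cytokine genes Il13 (-2.26 ± 0.37), Il4 (-1.79 ± 0.34) and Il5 (-1.26 ± 0.23) were among them with Il10, the receptor gene Il4ra (-0.84 ± 0.12) and the lineage regulator Gata3 (-0.74 ± 0.15). The Th1 effector list did not pass (20 measured, mean shift -0.11, median -0.34, camera adjusted p = 0.0647). Il2 was higher and 3 genes were lower, against 4 higher and 7 lower adjusted over the list alone. The 3 lower genes were Stat4, the transducer of IL-12 signals (-0.89 ± 0.10), the receptor gene Il12rb2 (-1.09 ± 0.17) and Gzmb, a cytotoxic protease (-1.43 ± 0.33). Ifng differed by -0.99 ± 0.25 (limma adjusted p = 0.0585) and Tbx21, the Th1 regulator, by -0.33 ± 0.17 (limma adjusted p = 0.323), so neither passed. In the regulatory T cell list (18 measured, mean shift -0.29, median -0.04, camera adjusted p = 0.436), Nrp1 was higher (1.10 ± 0.20) and Il10, Ctla4 (-1.25 ± 0.08) and Entpd1 (-1.45 ± 0.26) were lower. Adjusted over the list alone, 3 were higher and 4 lower. Foxp3, the regulator of that lineage, had means of 3.50 and 3.77 and did not pass (0.27 ± 0.13, limma adjusted p = 0.267).

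Cell cycle transcripts were higher in deficient cells: all 31 measured members lay above 0 (mean shift 0.49, camera adjusted p = 1.19e-16, adjusted p = 0.450 with an estimated correlation). Of these, 15 were higher by limma's adjusted p over all genes, 0 were lower and 16 did not pass, and 25 were higher adjusted over the list alone. The replication genes Mcm3 (0.76 ± 0.10), Mcm5 (0.56 ± 0.09), Pcna (0.52 ± 0.08) and Rrm2 (0.58 ± 0.09) were among the 15. Cell cycle inhibitors were lower as a list (14 measured, mean shift -0.31, camera adjusted p = 0.0136, adjusted p = 0.531 with an estimated correlation). Of these, 4 were lower, 2 higher and 8 did not pass, or 6 lower and 2 higher adjusted over the list alone. Btg2 (-1.26 ± 0.16), Ccng2 (-1.04 ± 0.13), Cdkn1b, which restrains cyclin-dependent kinases (-0.88 ± 0.14), and Rbl2 (-0.51 ± 0.11) were lower, and Cdkn2c (0.73 ± 0.14) and Rbl1 (0.43 ± 0.09) were higher. This list's call ended without wild-type mock replicate 2 (-0.28, camera adjusted p = 0.0579).

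Type I interferon response genes, which restrict viruses, were higher (20 measured, 19 above 0, mean shift 1.06, camera adjusted p = 1.25e-09, adjusted p = 0.450 with an estimated correlation). By limma's adjusted p 7 were higher, 0 lower and 13 did not pass, and 15 were higher adjusted over the list alone. Besides Rtp4 and Ifit1 the 7 held Ifi27l2a (1.32 ± 0.15), Ifit2 (1.04 ± 0.15), Ifit3 (0.89 ± 0.17) and Irf7, a regulator of the response (1.36 ± 0.28). Sterol synthesis genes lay higher as a list (14 measured, 13 above 0, mean shift 0.35, camera adjusted p = 0.000722, adjusted p = 0.600 with an estimated correlation). However, 0 members passed limma over all genes, 5 had an unadjusted limma p under 0.05 and 2 were higher adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, differed by 0.56 ± 0.13 (limma adjusted p = 0.0509) and Idi1 by 0.50 ± 0.13 (limma adjusted p = 0.0699). The sterol call ended without wild-type mock replicate 1 (0.16, camera adjusted p = 0.0689) and without deficient mock replicate 2 (0.19, camera adjusted p = 0.0548), and the shift was 0.55 without wild-type mock replicate 2.

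Hypoxia response genes were lower in deficient cells, with all 14 measured members below 0 (mean shift -0.54, camera adjusted p = 1.27e-05, adjusted p = 0.450 with an estimated correlation). Of the 14, 2 were lower by limma's adjusted p, 0 higher and 12 did not pass, and 6 were lower adjusted over the list alone. The 2 were Ero1a, an oxidase of protein folding (-1.43 ± 0.33), and Bnip3, a mitochondrial protein of mitophagy (-0.72 ± 0.16). Without wild-type mock replicate 2 the hypoxia shift was -0.35 (camera adjusted p = 0.00432). Glycolysis genes were lower as a list (15 measured, mean shift -0.31, camera adjusted p = 0.00180, adjusted p = 0.600 with an estimated correlation). The glucose transporter gene Slc2a3 (-1.39 ± 0.14) and the aldolase gene Aldoc (-1.18 ± 0.24) were lower, 0 were higher and 13 did not pass. Adjusted over the list alone 4 were lower. That list's call ended without wild-type mock replicate 2 (-0.22, camera adjusted p = 0.0759) and without deficient mock replicate 1 (-0.15, camera adjusted p = 0.146).

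TGF-beta signalling genes were lower (22 measured, mean shift -0.32, camera adjusted p = 0.0125, adjusted p = 0.450 with an estimated correlation). Among them 4 were lower, 0 higher and 18 did not pass, or 6 lower adjusted over the list alone. The 4 were Tgfb3, Id2, an inhibitor of helix-loop-helix factors (-1.08 ± 0.20), Ltbp3, which binds latent ligand (-1.07 ± 0.21), and the receptor gene Tgfbr2 (-0.55 ± 0.13, limma adjusted p = 0.0491). With the mean of each gene's probe sets the list's call ended (-0.29, camera adjusted p = 0.0524). The list of CD4 T cell genes was lower (11 measured, mean shift -0.21, camera adjusted p = 0.0172, adjusted p = 0.600 with an estimated correlation). Thy1 was lower (-0.73 ± 0.10), 0 members were higher and 10 did not pass, and adjusted over the list alone 1 was lower. Its call ended without deficient mock replicate 2 (-0.16, camera adjusted p = 0.0582).

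Published targets of the miR-17 family, which the design expects to be higher without the cluster, did not pass as a list and lay lower on average (31 measured, 11 above and 20 below 0, mean shift -0.19, median -0.15, camera adjusted p = 0.0563). Of the 31, 2 were higher, 6 lower and 23 did not pass by limma's adjusted p, against 3 higher and 7 lower adjusted over the list alone. The higher genes were E2f1, a driver of S phase (0.60 ± 0.13), and Rbl1, a pocket protein that binds E2F factors (0.43 ± 0.09). Txnip, which limits glucose uptake (-1.15 ± 0.12), the autophagy kinase gene Ulk1 (-0.82 ± 0.12), Stat3 (-0.70 ± 0.13), Bcl2l11, which encodes the death factor BIM (-0.92 ± 0.22), Rbl2 and Tgfbr2 were lower. Creb1 (0.06 ± 0.14, limma adjusted p = 0.852) and Cdkn1a (-0.45 ± 0.20, limma adjusted p = 0.25) did not pass. The list was called lower without wild-type mock replicate 1 (-0.18, camera adjusted p = 0.0496), without deficient mock replicate 1 (-0.21, camera adjusted p = 0.0397) and without deficient miR-17 replicate 1 (camera adjusted p = 0.0400) or 2 (camera adjusted p = 0.0397). It was also called lower with dim genes left out, the arrays scaled again or a term for the replicate number (camera adjusted p = 0.0117 to 0.0404), but not with the mean of probe sets, nor with an estimated correlation (adjusted p = 0.450). Bcl2l11 differed by -0.55 without deficient mock replicate 2 and was called in 1 of the 4 fits that left out a wild-type mock or deficient mock array. E2f1, Tgfbr2, Stat3 and Rbl2 lost the call whichever wild-type mock or deficient mock array was left out, whereas Txnip kept it each time. The miR-19 family list did not pass (14 measured, mean shift -0.14, camera adjusted p = 0.179), with Rnf11 higher (1.21 ± 0.22) and Tnfaip3, Bcl2l11 and Tgfbr2 lower, also adjusted over the list alone (1 higher, 3 lower).

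The other lists did not pass the list test, and their called members were few. Th17 (mean shift -0.52) held Batf, a factor of effector differentiation (-1.50 ± 0.14). The follicular helper list, whose mean shift (-0.27) and median (0.00) differed in sign, held Bcl6 (-1.46 ± 0.31). Bcl6 differed by -0.97 without wild-type mock replicate 1 and was called in 1 of the 4 fits. Its other probe set, nearly as bright (mean 4.88 against 4.94), read -0.41. The naive and memory list (mean shift -0.23) held the IL-7 receptor gene Il7r (-1.36 ± 0.09), Satb1 (-0.75 ± 0.15) and Foxo1 (-0.56 ± 0.10). In the early activation list (mean shift -0.06) Myc (1.12 ± 0.21) and Nr4a1 (0.68 ± 0.13) were higher and Junb (-0.85 ± 0.10) and Tnfrsf9 (-0.81 ± 0.17) lower. In the inhibitory receptor list (mean shift -0.25) Cd200 was higher (0.72 ± 0.10) and Ctla4 and Havcr2 (-0.65 ± 0.12) lower. Apoptosis (mean shift -0.14) held Birc3 (-0.55 ± 0.13), Birc2 (-0.50 ± 0.12) and Bcl2l11, and the PI3K and Akt list (mean shift -0.11) Foxo1 and Inpp5d (-0.43 ± 0.10), all lower. MicroRNA processing (mean shift -0.20) held Tarbp2 (-0.94 ± 0.11) and the unfolded protein response (mean shift 0.07) Xbp1 (-0.41 ± 0.10). Among p53 targets (mean shift -0.15) and ribosomal proteins (mean shift -0.03) limma called 0 members, with 5 and 0 at an unadjusted p under 0.05. Mcm7, the host gene of a paralogous cluster and the only measured member of its list, was higher (0.50 ± 0.07).

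Markers of other cell types did not pass as lists in this comparison. Mean shifts were -0.11 for B cells, with Ighm lower (-1.02 ± 0.10), and -0.07 for macrophages and monocytes, with Ctss higher (0.77 ± 0.13) and Fcgr3 lower (-1.27 ± 0.21). They were -0.15 for dendritic cells, -0.45 for CD8 T cells, -0.45 for NK cells and -0.02 for neutrophils. Gzma, shared by the CD8 and NK lists, read 9.58 and 6.53 on the wild-type mock arrays and did not pass (-2.99 ± 0.82, limma adjusted p = 0.0746). The 4 measured erythroid genes, Hba-a1, Alas2, Slc4a1 and Epb42, differed by -0.23 to 0.01. Sex-linked transcripts did not differ as a list (mean shift -0.05). The poly-A controls spiked into the samples were lower on the deficient mock arrays by a mean of -0.57 across 24 of 24 probe sets, in the same comparison as each gene group above. Probe sets for the 3' and 5' ends of Gapdh differed by -0.14 to 0.03 log2 units on the 6 arrays and those of actin by 0.23 to 0.47. The hybridization controls were lower on the deficient mock arrays by -0.17 in 18 of 18 probe sets.

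**Figure D1:**
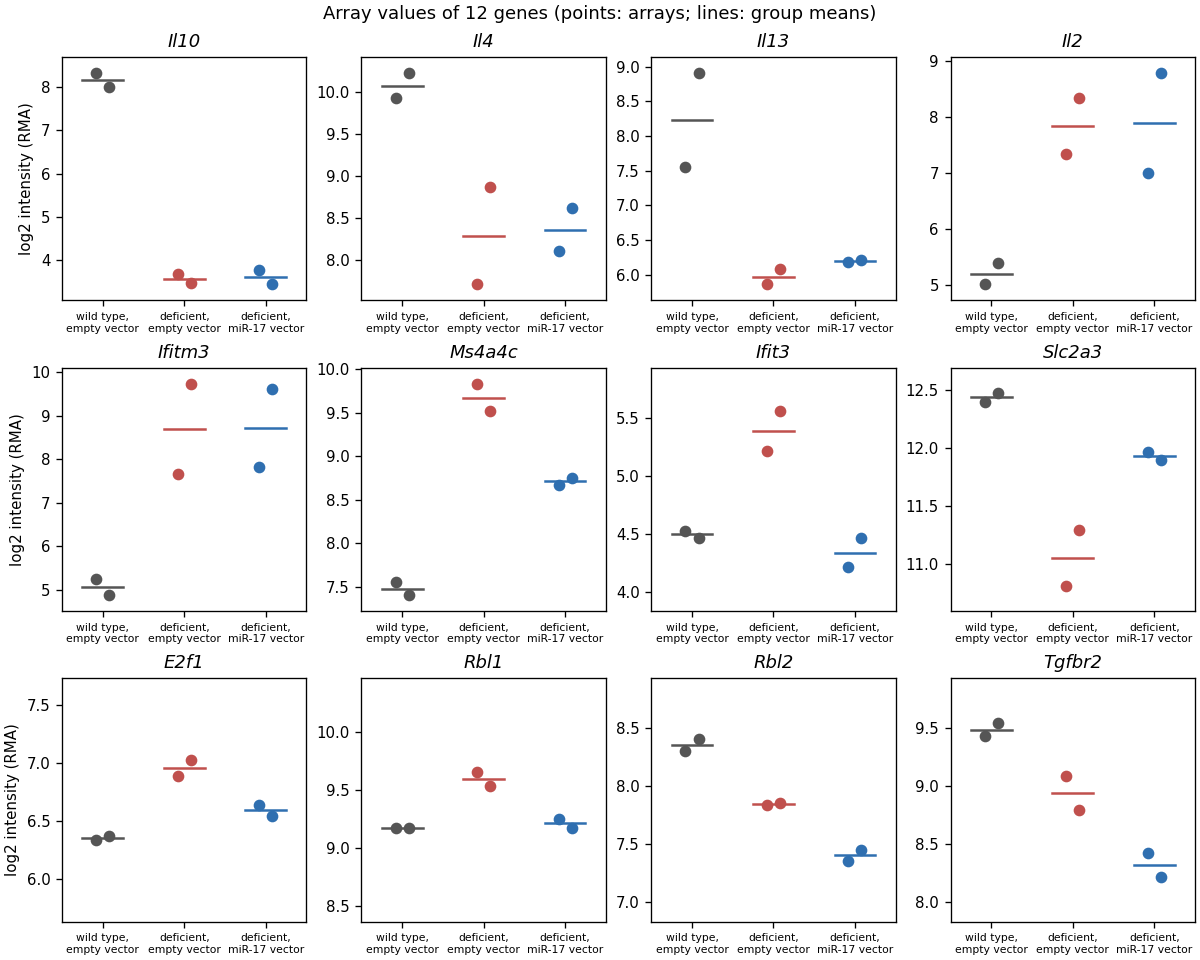
Log2 intensities of 12 genes on each array (points) with group means (lines) for wild-type mock, deficient mock and deficient miR-17 cells, 2 arrays per group. Il10 read about 8.17 in wild-type mock cells and 3.58 and 3.62 in the deficient groups, whereas Tgfbr2 and Rbl2 were lowest in deficient miR-17 cells.

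The second comparison, deficient miR-17 against deficient mock, asked what changes when miR-17 alone is returned. Without a term for the replicate number, limma called 0 genes (smallest adjusted p = 0.428). With such a term some genes were called, Plek, Ms4a4c, Anapc11, Ifit3 and Slc2a3 among them, but the labels do not tie the numbers to a shared animal or batch. The smallest adjusted p in that fit was that of Cth, a gene outside the fixed rule (1.74 ± 0.09, limma adjusted p = 0.00270). At an unadjusted p under 0.05 without that term there were 487 genes, 237 higher and 250 lower, where chance gives 620 for independent arrays. Differences between replicates 1 and 2 correlated across genes at 0.634 between these 2 groups, so 620 is no exact baseline. The published miR-17 family targets shifted down as a list, with 26 of 31 members below 0 (mean shift -0.14, camera adjusted p = 2.76e-06, adjusted p = 0.633 with an estimated correlation). By limma over all genes 0 of the 31 were called, 7 had an unadjusted p under 0.05, and 4 were lower adjusted over the list alone. These 4 were Tgfbr2, the type II receptor of TGF-beta (-0.62 ± 0.13), Jak1, a kinase of cytokine receptors (-0.53 ± 0.12), Rbl2 (-0.44 ± 0.11) and Rbl1 (-0.39 ± 0.09). Dimmer probe sets of Tgfbr2 (-0.08 and 0.10), Jak1 (-0.06) and Rbl1 (-0.003) read nearer 0. Other sets of Jak1 (-0.62) and Rbl2 (-0.32) were lower too. With a term for the replicate number Jak1 was called over all genes. The list's mean level on the arrays was 7.88 and 7.85 in wild-type mock, 7.69 and 7.64 in deficient mock and 7.57 and 7.5 in deficient miR-17 cells.

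Type I interferon response genes also shifted down on return of miR-17, with 19 of 20 members below 0 (mean shift -0.37, camera adjusted p = 2.14e-06, adjusted p = 0.805 with an estimated correlation). Limma called 0 of them, 3 had an unadjusted p under 0.05 and 2 were lower adjusted over the list alone. Differences were -1.05 ± 0.17 in Ifit3, -0.58 ± 0.10 in Irf9, -0.68 ± 0.28 in Irf7 and -0.37 ± 0.16 in Stat2. Glycolysis genes shifted up, with 13 of 15 above 0 (mean shift 0.26, camera adjusted p = 4.21e-07, adjusted p = 0.805 with an estimated correlation). Limma called 0 of them, 4 had an unadjusted p under 0.05 and 1 was higher adjusted over the list alone, Slc2a3 (0.88 ± 0.14). Beside it stood differences of 0.36 ± 0.12 in Pfkl, 0.47 ± 0.16 in the lactate transporter gene Slc16a3 and 0.24 ± 0.10 in Hk1. Hypoxia response genes shifted up, with 12 of 14 above 0 (mean shift 0.30, camera adjusted p = 0.000158, adjusted p = 0.805 with an estimated correlation). Limma called 0 of them over all genes and 0 adjusted over the list alone, and 4 had an unadjusted p under 0.05: Ero1a (0.86 ± 0.33), Vegfa (0.60 ± 0.25), Bnip3 (0.38 ± 0.16) and Egln1 (0.36 ± 0.13). With a term for the replicate number Ifit3, Irf9, Slc2a3 and Ero1a of these 3 lists were called. The glycolysis shift was 0.11 (camera adjusted p = 0.0461) without deficient mock replicate 1 and 0.41 without replicate 2, and the interferon shift -0.62 without deficient mock replicate 1 and -0.67 without deficient miR-17 replicate 2. The interferon call ended without deficient mock replicate 2 (-0.13) and without deficient miR-17 replicate 1 (-0.08), and the hypoxia call without deficient mock replicate 1 (0.16). Such fits compare unequal replicate numbers, so a difference by number shared by the groups enters these shifts. The interferon list's mean level on replicates 1 and 2 was 7.18 and 7.67 in deficient mock cells. In deficient miR-17 cells it was 6.77 and 7.34, lower at both numbers.

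Among single genes, the smallest unadjusted p-values on the higher side belonged to Plek (0.91 ± 0.12), Lgals7 (0.86 ± 0.13), Slc2a3, Tpcn1 (0.64 ± 0.11), Sdc4 (1.0 ± 0.19, but 0.05 on its other probe set), Aqp3 (0.89 ± 0.18), Cyb5r3 (0.47 ± 0.10) and Ckb (0.57 ± 0.13). On the lower side they belonged to Ms4a4c (-0.96 ± 0.13), Ankib1 (-0.79 ± 0.12), Anapc11 (-0.81 ± 0.13), Ifit3, Tmem123 (-0.64 ± 0.10), Ginm1 (-1.12 ± 0.18), Cep55 (-0.56 ± 0.10) and Crot (-0.67 ± 0.11). Limma's adjusted p for these 16 lay between 0.428 and 0.775, so none passed without a term for the replicate number, and most of them passed with it. Il10, Ctla2b, Il2 and Ifitm3, with large differences in the first comparison, did not pass here with or without a term for the replicate number. They differed by 0.04 ± 0.18, -0.01 ± 0.16, 0.05 ± 0.54 and 0.02 ± 0.71. Values were further from 0 for Selenbp1 (1.37 ± 0.61), Ier3 (0.96 ± 0.44), Ifit1 (-0.82 ± 0.42) and Rtp4 (-0.77 ± 0.43), and for Sdc4 and Ms4a4c above. Of these only Ms4a4c passed with that term. E2f1 differed by -0.36 ± 0.13, Bcl2l11 by 0.17 ± 0.22, Creb1 by 0.10 ± 0.14, Cdkn1a by -0.08 ± 0.20, Ifng by -0.42 ± 0.25, Tbx21 by -0.26 ± 0.17 and Foxp3 by -0.28 ± 0.13, none of them past the test.

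In the fit without that term every other list failed the list test, with camera adjusted p of 0.0926 or more and 0 members called by limma without a term for the replicate number, against Sesn3 of the PI3K and Akt list and Nkg7 of the NK list with it. Mean shifts were -0.10 for miR-19 family targets, 0.08 for TGF-beta signalling, -0.10 for Th1 effectors, 0.04 for regulatory T cells, and 0.03 for Th2. They were -0.06 for Th17, 0.01 for follicular helper, 0.08 for naive and memory, 0.03 for early activation and 0.01 for inhibitory receptor genes. Cell cycle genes shifted by a mean of -0.02, cell cycle inhibitors by -0.04, apoptosis genes by 0.05, PI3K and Akt genes by -0.02 and p53 targets by 0.00. The means were 0.12 for sterol synthesis with 14 of 14 above 0, 0.11 for the unfolded protein response, -0.02 for ribosomal proteins and 0.00 for microRNA processing. Among cell type markers they were -0.01 for B cells, -0.05 for macrophages and monocytes, 0.14 for dendritic cells, -0.12 for CD8 T cells, -0.09 for NK cells, -0.10 for neutrophils, -0.07 for CD4 T cells and 0.02 for sex-linked transcripts. The mean shift, the median or the test differed in sign in 6 of these lists: follicular helper, cell cycle, PI3K and Akt, p53 targets, microRNA processing and B cell. The groups' arrays did not overlap for 28.9% of genes, where chance gives 33.3% for independent arrays, which these were not.

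**Figure D2:**
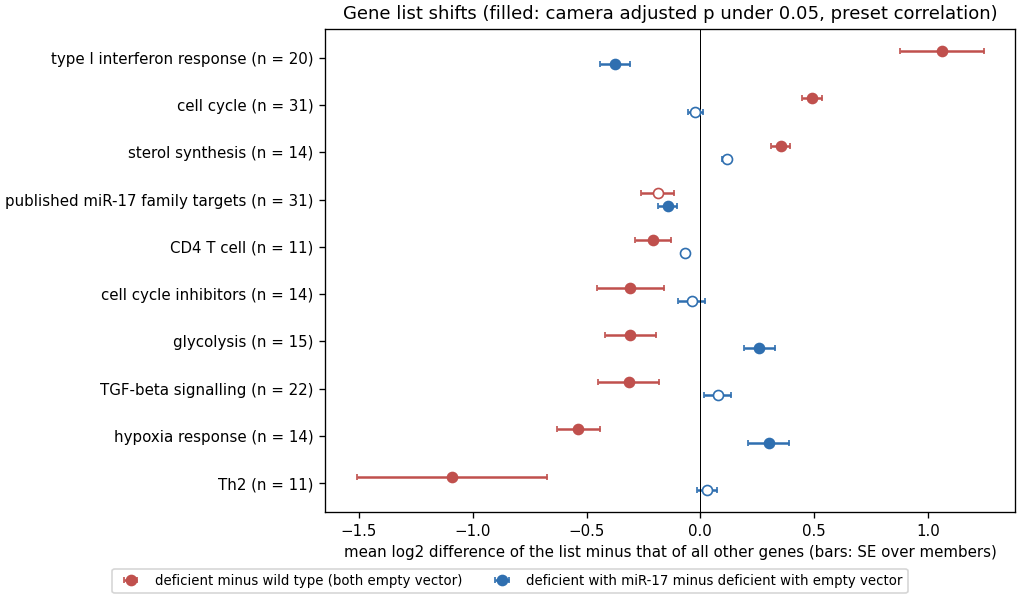
Mean log2 difference of each gene list minus that of all other genes, with bars of 1 SE over the list's members, for deficient mock minus wild-type mock and deficient miR-17 minus deficient mock, for the lists called in either comparison. Filled points passed camera with the preset correlation, and 0 passed with an estimated one. The interferon list read 1.06 and then -0.37, and the miR-17 family targets -0.19 and then -0.14.

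The design looks for targets of miR-17 among genes that are higher without the cluster and lower again once miR-17 is back. Without a term for the replicate number limma called 0 genes in both comparisons at adjusted p, whereas some were called with it. At unadjusted p under 0.05 in both, 96 genes had this pattern and 97 the mirror pattern. Both comparisons use the deficient mock arrays, and 100 simulations of unchanged arrays gave 68.9 (54 to 89) and 69.1 (45 to 90) such genes on average. Independent lists would give 32.0 and 20.8. The simulation shared the arrays in the same way, so the sharing is already in its counts but not in those of independent lists. It held no genotype effect, so it is no baseline for genes that differ by genotype and cannot say what the return of miR-17 adds. Divided between the comparisons, the 2 shared arrays leave 1 for each, so the observed 96 and 97 were not counted again that way. Without deficient miR-17 replicate 1 the counts were 48 and 47. Leaving out the predicted gene D030056L22Rik (0.65, then -0.57), which ranked ahead of Lpgat1, the 10 higher-then-lower genes with the smallest p-values began with Ms4a4c (2.19 ± 0.13, then -0.96 ± 0.13), Ifit3 (0.89, then -1.05), Anapc11, a subunit of the anaphase-promoting complex (0.66, then -0.81), Cep55, needed in cytokinesis (0.48, then -0.56), and Kpna2, a nuclear import receptor (0.47, then -0.36). The others were Mfn2, a mitochondrial fusion protein (0.54, then -0.58), Selp (1.33, then -0.85), Derl2 (0.58, then -0.63), Akap12 (1.33, then -0.61) and Lpgat1 (0.60, then -0.57). Another probe set of Derl2 did not repeat the pattern (-0.06, then -0.07), and that of Mfn2 was nearly level at first (0.03, then -0.31). Further sets of Ms4a4c, Cep55, Selp and Lpgat1 repeated it in direction, except a set of Lpgat1 (0.24, then 0.03). Of the listed miR-17 family targets only E2f1 and Rbl1 had the pattern, and Vegfa the mirror pattern. The other probe set of E2f1 repeated it in direction (0.80, then -0.58), whereas that of Rbl1 did not fall (0.49, then -0.003). The cell cycle genes Ccne2, Mcm3 and Rrm2 and the interferon genes Irf7 and Irf9 had the higher-then-lower pattern too, beside E2f1 and Ifit3 of those lists. The mirror pattern held the glycolysis genes Slc2a3, Hk1 and Slc16a3 and the hypoxia genes Bnip3 and Ero1a. In both steps 13 genes were higher and 20 lower, where the simulation gave 1.24 (0 to 5) and 1.31 (0 to 6) and independent lists would give 30.3 and 21.9.

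Across genes, which are not independent replicates, the fold changes of the 2 comparisons correlated at r = -0.214. In the simulated unchanged arrays, which held no genotype difference, r was -0.500. Their covariance was -0.0116, against a simulated -0.0119 (-0.0128 to -0.0112), or -0.00555 where the simulated spread came from a model with a term for the replicate number. With the deficient mock arrays divided between the comparisons, r was -0.212 in one arrangement and 0.225 in the other.

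**Figure D3:**
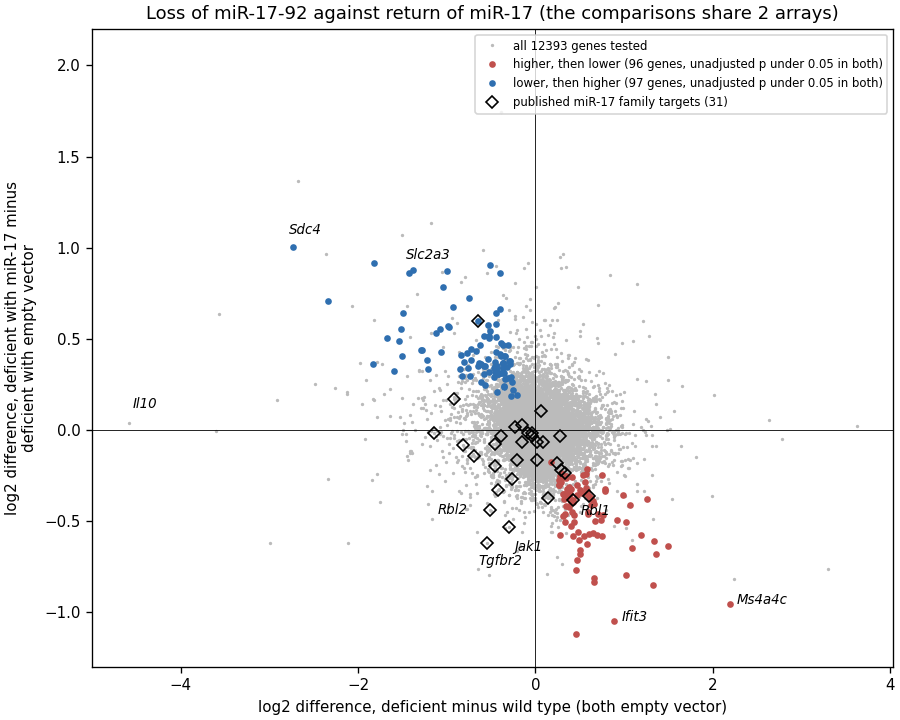
Log2 difference of deficient miR-17 from deficient mock cells (y) against that of deficient mock from wild-type mock cells (x) for 12393 genes, with the 96 higher-then-lower and 97 lower-then-higher genes and the 31 miR-17 family targets marked. Both axes use the deficient mock arrays, which alone gives a negative slope; Tgfbr2, Rbl2 and Jak1 lay below 0 on both axes.

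The third comparison, deficient miR-17 against wild-type mock, shows what still differed from wild type once miR-17 was back, with genotype and vector both different. Il10 (-4.55 ± 0.18, limma adjusted p = 0.000144), Ctla2b (-3.61 ± 0.16) and Gzma, a cytotoxic protease (-3.61 ± 0.82, limma adjusted p = 0.0427), had the largest decreases as read. The deficient miR-17 mean of Il10 was 3.62, again at a level that background can set, and Gzma differed by -2.08 without wild-type mock replicate 1. Ifitm3 (3.64 ± 0.71), Drc1 (2.73 ± 0.17) and Il2 (2.69 ± 0.54) were the largest increases. Tgfbr2 was lower by -1.17 ± 0.13 (limma adjusted p = 0.00741), Rbl2 by -0.95 ± 0.11 and Ifng by -1.41 ± 0.25 (limma adjusted p = 0.0214). In total 500 genes were higher and 343 lower, with 2820 at an unadjusted p under 0.05. Arrays of the groups did not overlap for 50.4% of genes, where chance gives 33.3% for independent arrays, which these were not. Of these 843, 98 were still called without wild-type mock replicate 1 and 369 without replicate 2. The counts were 416 without deficient miR-17 replicate 1 and 74 without replicate 2.

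Both comparisons against wild-type mock called 334 genes higher and 240 lower alike and 0 in opposite directions. The simulation held no difference between groups, so its counts of 0.01 and 0.07 were near 0 by construction. Independent lists would share 18.7 and 9.58. The counts were not made again with a different wild-type array in each comparison, so part of the excess over independent lists can come from the sharing. The miR-17 family targets were lower here (mean shift -0.33, camera adjusted p = 0.000132, adjusted p = 0.487 with an estimated correlation). They held 0 higher and 8 lower members, or 10 lower adjusted over the list alone. Also lower were Th2 (-1.06, adjusted p = 0.487 with an estimated correlation), Th1 effector (-0.21, adjusted p = 0.487 with an estimated correlation), and cell cycle inhibitor genes (-0.34, adjusted p = 0.593 with an estimated correlation). So were CD4 T cell (-0.27, adjusted p = 0.593 with an estimated correlation) and hypoxia genes (-0.24, adjusted p = 0.598 with an estimated correlation). Cell cycle (0.47, adjusted p = 0.593 with an estimated correlation), sterol synthesis (0.47, adjusted p = 0.598 with an estimated correlation) and interferon genes (0.69, adjusted p = 0.598 with an estimated correlation) were higher. The poly-A controls also differed here, with means of 7.46 and 7.02 on the deficient miR-17 arrays and 7.93 and 7.63 on the wild-type mock arrays. Counts over all genes and adjusted over the list alone were 6 and 7 lower for Th2, 13 and 23 higher for cell cycle, 3 and 8 higher for sterol synthesis, 3 and 3 higher for interferon genes, 1 and 1 lower for hypoxia and 1 and 4 lower for CD4 T cell genes. For cell cycle inhibitors they were 0 higher and 4 lower against 1 and 5, and for Th1 effectors 1 higher and 5 lower against 3 and 10. Without wild-type mock replicate 1 the sterol shift was 0.27 and the hypoxia shift -0.42, and without deficient miR-17 replicate 2 the interferon shift was 0.40 (camera adjusted p = 0.0107). The hypoxia call ended without wild-type mock replicate 2 (-0.05, camera adjusted p = 0.639) and without deficient miR-17 replicate 1 (-0.19, camera adjusted p = 0.114), and with the mean of probe sets (-0.22, camera adjusted p = 0.0613). With the lowest 50% of genes left out the Th1 (-0.06, camera adjusted p = 0.0522) and interferon (0.68, camera adjusted p = 0.0527) calls ended. Across the 3 comparisons camera with the preset correlation called 9, 4 and 9 of the 31 tested lists, and 0 of these calls held with an estimated correlation. Fry, which asks whether a list moves one way on balance, called 0, 0 and 3, the 3 being the miR-17 family targets, Th1 effector and Th2 lists against wild type.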

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

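The simulation whose spread came from the model with the replicate number as a term was chosen after the results were seen, and all other alternatives were planned. The cause of each change below was not tested, except that leaving out arrays, a filter, a fold minimum or a looser threshold changes the number of samples or genes by construction. Across alternatives, 121 of 158 gene counts stayed within 1.5 times the reported count, and of gene differences 2078 kept direction and side of the threshold, 288 lost the call, 49 gained it and 6 turned sign. With single arrays left out, deficient mock against wild-type mock gave 23 to 391 higher and 72 to 302 lower genes, and deficient miR-17 against wild-type mock 21 to 394 and 53 to 303. Reciprocal genes then numbered 48 to 100 (higher, then lower) and 47 to 113. The number of lower lists then ranged from 5 to 12 (deficient mock against wild-type mock), 1 to 3 (deficient miR-17 against deficient mock) and 7 to 10 (deficient miR-17 against wild-type mock), and that of higher lists in deficient miR-17 against deficient mock from 2 to 4. The miR-17 family targets shifted by -0.214 to -0.163 in deficient mock against wild-type mock. An adjusted p under 0.10 gave 876 higher and 569 lower genes in deficient mock and 961 and 578 in deficient miR-17 against wild-type mock. A minimum of 1.5-fold gave 303 higher genes in deficient mock cells, the mean of probe sets 333 in deficient miR-17 cells, eBayes without trend 293 and 267, and leaving out the lowest 50% of genes 63 lower-then-higher genes. The target list, not called in deficient mock against wild-type mock, was called with the lowest 25% (-0.20) or 50% (-0.24) left out, quantile normalization again (-0.22) or median centring (-0.19), and in 4 of the 6 fits that left out an array. With an estimated correlation 0 lists were called in any comparison. Camera at that setting gave adjusted p = 0.633 for the targets in deficient miR-17 against deficient mock (-0.14) and 0.487 against wild-type mock (-0.33). Fry gave 0.747 for the former and called 0 lists, except 3 lower ones against wild-type mock.

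The replicate numbers, shared by the groups, are not tied by the labels to an animal or batch, and only 2 exist, so what they mark is open. The values below nevertheless show a difference by number that the groups share. Replicate 2 arrays read lower than replicate 1 arrays in 24 of 24 poly-A control sets (-0.372 on average) and 18 of 18 hybridization control sets (-0.343). Same-numbered deficient mock and deficient miR-17 arrays correlated at 0.997 and 0.996, above the within-group values (0.994 to 0.995). Differences between replicates 1 and 2 correlated across genes between groups at 0.429, 0.506 and 0.634. With the replicate block, limma called 1661 higher and 1062 lower genes (deficient mock against wild-type mock), 15 and 23 (deficient miR-17 against deficient mock) and 1890 and 1093 (deficient miR-17 against wild-type mock), and all 810 and 843 reported calls were among them. Reciprocal genes numbered 210 and 291, and 17 and 12 at adjusted p. The replicate block gave 4 higher lists in deficient miR-17 against deficient mock and called the targets in deficient mock against wild-type mock (-0.19, camera adjusted p = 0.0393).

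With different deficient mock arrays in the 2 comparisons, the fold changes correlated across genes at -0.212 (replicate 1 with wild type) and 0.225 (replicate 2 with wild type), with covariances of -0.0126 and 0.0192. The observed minus simulated covariance was 0.000295, and -0.00605 with the spread from the fit with the replicate block. Differences that turned sign were uncalled throughout: Creb1 in deficient mock against wild-type mock (-0.028 to 0.155 with single arrays left out, below 0 without wild-type mock replicate 2 and deficient mock replicate 1) and on return of miR-17 (-0.019 with the mean of probe sets). Likewise on return of miR-17 Bcl2l11 ranged from -0.207 to 0.548 (below 0 without deficient mock replicate 2) and Cdkn1a from -0.359 to 0.199 (above 0 without deficient mock replicate 2 and deficient miR-17 replicate 1). For low signals such as Foxp3 and Il10 in deficient cells, array background limits how small a level can be read. The planned choices of seed site and 3' untranslated region were not run, since no transcript sequence was used here.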

Other observations

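Of the tests below, those of single arrays, of miR-17 dose and of other cell types were chosen after the result was seen.

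The miR-17 family targets were lower in deficient miR-17 than in deficient mock cells, and 0% of 10000 random lists matched on mean level lay at or below their mean of -0.137 (random median 0.0153, lowest -0.0942), which argues against a drift of genes of that brightness. Leaving out single arrays argues against 1 array deciding the shift, since it was still -0.115 in the fit that lowered it most, without deficient miR-17 replicate 2. A biological hypothesis is that the vector may have given more miR-17 activity than wild-type cells have: the list lay -0.331 below wild-type mock. This cannot be told apart from other effects of genotype, since the list already lay -0.19 below wild type in deficient mock cells, and the level of miR-17 was not analysed here. The shift also has no call with an estimated correlation, where the unadjusted camera p was 0.0204 against 2.67e-07 with the preset one. A lost call need not mean correlated genes, and the estimate for this list was 0.0233. The lost call therefore cannot decide whether co-regulation of the list's genes adds to the shift, and that stays open.

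Interferon response genes were higher in deficient mock than in wild-type mock cells, and the shift was still 0.812 in the fit that lowered it most, without deficient mock replicate 2, which argues against 1 array as the whole cause. A candidate source is RNA from other cell types left by the sort for CD4+CD25- cells, which would remove most of them. Members of the B cell, macrophage and monocyte, and dendritic cell lists differed by -0.110 on average (SE 0.0679, n = 36 genes, 24 below 0), but they went both ways, so such cells cannot be told apart from a difference within T cells. In deficient mock cells Lyz2 read 3.59, Cd79a 4.80, H2-Aa 5.62 and Cd74 7.24. A difference in the animals' exposure to virus or in the response to the vector stays open and was not tested.

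Genes called between deficient mock and wild-type mock cells could partly reflect sequence from another mouse strain kept around the deleted locus. Among the 100 measured genes nearest to it 10 were called, against 6.51% of the other 12293 (odds ratio 1.60, 95% interval 0.737 to 3.09, one-sided Fisher's exact p = 0.118). The interval holds both no excess and a clear one, so strain sequence and deletion cannot be told apart for these 10. They were Dis3 (0.82), Ndfip2 (0.53) and Tdrd3 (0.59), higher, and Cysltr2 (-0.99), Dok2 (-0.47), Elf1 (-0.79), Itm2b (-0.33), Piwil2 (-1.01), Ppp3cc (-0.80) and Rgcc (-0.80), lower.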
